A study of Arabidopsis thaliana with 15 samples.

How the data were processed

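Total RNA of whole roots from 15 pools of Arabidopsis thaliana seedlings was measured on Affymetrix AraGene 1.0 ST arrays, 1 array per pool. The seedlings were 10 days old, had the Wassilewskija background and carried a 14-3-3κ:GFP fusion under the CaMV 35S promoter. They were fixed with RNAlater inside Kennedy fixation tubes on board a C-9 aircraft, either in level flight or after 1, 3 or 10 parabolas. Per the labels, the pools of each condition came from 1 tube, and RNA was treated with DNase and labelled as sense-strand DNA. The submitters' processing notes name RMA, oligo, limma, R 4.0.0 and TAIR10 without saying what each was used for. The deposited values are log2 expression values per probe set after the authors' RMA, which corrects background, scales arrays to each other and summarises probes. Filters applied by the authors are not given in the sources used here.

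The table held 38408 rows for the 15 arrays and 0 columns of other samples. The annotation supplied with the table gave exactly 1 gene to 16722 rows, several genes to 759 rows and no gene to 20927 rows. Where a gene had more than 1 row, which was the case for 146 genes, the row with the highest mean over all arrays was kept. This left 16550 genes, and no filter on dim signals was used. Gene names came from that annotation and from a reference table of the assembly TAIR10.1, to which 16574 rows were matched by gene number. Because that assembly is not the TAIR10 named by the submitters, no coordinates are given. A gene with no symbol is named by its locus, which was the case for 14745 genes. Array medians over all rows lay between 3.70 and 3.89 on the log2 scale, and between 3.65 and 3.70 over the tested genes. The number of arrays limits the precision of every value.

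The groups were level flight (n = 4), parabola 1 (n = 4), parabola 3 (n = 4) and parabola 10 (n = 3). Group means were fitted to the log2 values of all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). There were 6 contrasts, namely each parabola group against level flight and each pair of parabola groups. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p under 0.05 were called changed. The limma F-test over the 3 contrasts against level flight gave 1 p-value per gene. Standard errors (SE) are those of the fitted log2 fold change, and standard deviations (SD) are between arrays.

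The comparisons, the tests, the rule for named genes and 26 gene lists were fixed before the data were examined. The rule took genes past the threshold whose groups did not overlap. From these it named the 10 largest rises and 10 largest falls against level flight, and the 5 largest of each between parabola groups. Up to 4 members of each list described were named too, by smallest p-value. Lists with at least 3 measured members were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The 9 lists tested were calcium sensors and touch genes, heat shock, auxin response, xyloglucan endotransglucosylases and expansins, hypoxia, abscisic acid with cold and dehydration, reference genes, chloroplast-encoded genes and mitochondrion-encoded genes. Most fixed members of several lists were not among the tested genes. Measured were 7 of 20 calcium sensors and touch genes, 5 of 21 heat shock genes and 6 of 16 auxin response genes. For xyloglucan endotransglucosylases and expansins 7 of 20 were measured, for hypoxia 3 of 16, and for abscisic acid, cold and dehydration 5 of 20. Results for these lists cover only the measured members. Another 9 lists had 1 or 2 measured members, which are reported as single genes. For 8 lists no member was among the tested genes: 14-3-3 genes, jasmonate, ethylene, light and flavonoid genes, and markers of the endodermis, xylem, phloem and meristem. The 14-3-3 genes, among them the transgene's own gene GRF8, are therefore not analysed here.

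Added after the data had been seen were 61 families of genes with a shared symbol and at least 5 measured members. Lists of class III peroxidases, VQ motif proteins, core hypoxia loci and nuclear photosynthesis genes were added too, without the members already seen. The alternatives fixed beforehand were median centring of arrays, a repeated quantile normalization, centring on the 3 measured reference genes, removal of the 25% of genes with the lowest mean, and use of all rows. Others were fits with the arrays of 2 groups alone, eBayes with trend and robust options, array weights, the replicate number as a block, stricter thresholds and omission of each array in turn. The median of unnamed rows as a covariate was added after the data had been seen. These unnamed rows are the 7083 rows numbered before the first annotated row, a part of the 20927 rows with no gene. Their array medians lay below those over all rows. Calls shared by contrasts with the same level arrays were compared with 100 simulated sets of unchanged groups and with contrasts that used separate pairs of level arrays.

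The steps were tested on simulated data with 200 changed genes per contrast, drawn as independent normal values with the mean and the SD within groups of each gene. A log2 change of 1 was recovered for 92.5% to 95.5% of such genes over the 6 contrasts, a change of 0.5 for 26.9% to 65.7%, and a change of 2 for 100%. False calls made up 4% to 9.68% of calls. With 9 lists shifted by 0.5 in turn in the parabola 10 arrays, camera called 9 of 9 and 0 of the lists left alone. The simulated genes were independent, so false list calls among correlated genes were not tested. In the real data the estimated correlation of the chloroplast-encoded genes was 0.626. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures with matplotlib 3.10.9.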

Results

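The series holds 15 arrays of whole roots of the pCaMV35S:14-3-3κ:GFP line, which makes the regulatory protein 14-3-3κ fused to a fluorescent reporter. Seedlings were carried in fixation tubes, holders that release a fixative onto the plants when actuated. There were 4 arrays of roots fixed in level flight, 4 after parabola 1, 4 after parabola 3 and 3 after parabola 10. A parabola is a flight manoeuvre with a phase of reduced gravity between phases of raised gravity. The study set each parabola group against level flight to find genes that respond to this kind of flight. All pools of a group came from 1 tube, so the p-values measure the spread among root pools from 1 tube, and group, tube and time on board cannot be separated. The first principal component of the tested genes held 33.2% of the variance and the second 11%. On the first, level arrays lay between −30.7 and −25.5 and the other arrays between −1.1 and 22.2. By the F-test over the 3 contrasts against level flight, 2601 of 16550 genes differed.

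**Figure D1:**
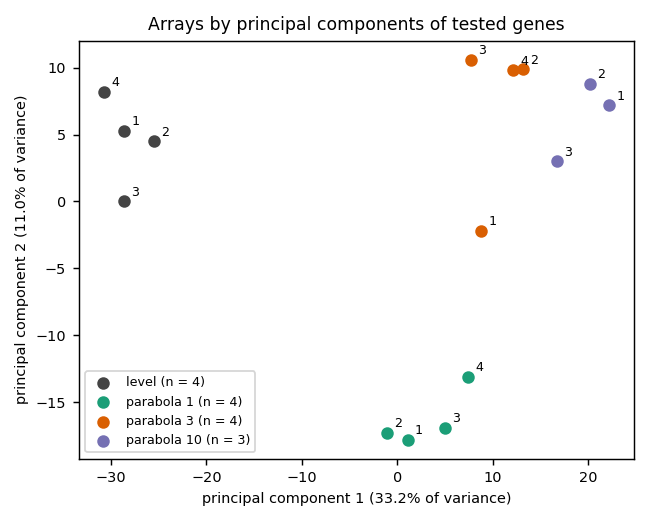
Each point is 1 array, placed by the first (33.2% of variance) and second (11%) principal components of the tested genes, coloured by group and labelled with its replicate number. The 4 level arrays lie between −30.7 and −25.5 on the first component, apart from all other arrays.

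After parabola 1, transcripts of the class III peroxidase gene AT1G49570 were 6.07-fold higher than in level flight (log2 fold change 2.60 ± 0.16 SE, n = 4 and 4, adjusted p = 7.34e-08). The gene for an extensin-like cell wall protein, AT1G26240, rose 3.87-fold (1.95 ± 0.30 SE). AT5G47980, an acyltransferase gene of the thalianol cluster, rose 3.42-fold (1.77 ± 0.19 SE), and the MADS-box gene AGL46 rose 2.95-fold (1.56 ± 0.16 SE). AT4G27654 was 8.09-fold lower (log2 fold change −3.02 ± 0.21 SE, n = 4 and 4, adjusted p = 1.25e-07). The glutaredoxin gene GRX480 was 4.92-fold lower (−2.30 ± 0.17 SE), and STZ, the zinc finger transcription factor also called ZAT10, was 4.56-fold lower (−2.19 ± 0.17 SE).

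The other largest rises after parabola 1 were AT3G62460, AT5G26290, AT3G29639, AT1G49200, AT3G61898 and AT4G25410, with log2 fold changes from 1.51 to 1.93. The other largest falls were AT4G27657, AT2G36690, AT5G62210, AT4G04745, the zinc finger gene AT3G53600, AT4G29780 and the VQ motif gene AT1G78410, with log2 fold changes from −2.72 to −2.22. In AT3G53600, parabola 1 replicate 3 lay at 3.51 and the other 3 arrays at 4.35 to 4.47. In all, 1378 genes changed, 575 upward and 803 downward, of which 55 and 202 changed at least 2-fold. The groups did not overlap in 14% of genes, where chance gives 2.86%.

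Of 20 fixed calcium sensors and touch genes 7 were measured, all of them calmodulin-like genes. After parabola 1, 4 of these fell and 3 did not pass the test, and 4 fell when adjusted over the list alone. The calmodulin-like genes CML38 (−2.13 ± 0.20 SE), AT1G76640 or CML39 (−2.11 ± 0.22 SE), CML37 (−0.71) and CML23 (−0.49) were those that fell. The list had a median log2 fold change of −0.49 and stood below other genes in camera (adjusted p = 0.000627, and adjusted p = 0.0219 with an estimated correlation). This was the only list call against level flight that held with an estimated correlation. Fry, which asks whether a list moves one way without comparing it with other genes, gave an adjusted p of 2.33e-05.

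Of 20 fixed genes of abscisic acid, cold and dehydration 5 were measured. KIN2 fell (−0.37 ± 0.11 SE), as did 1 when adjusted over the list alone. COR47 (−0.27), COR15A (−0.23) and LTI30 (−0.15) did not pass. The list median was −0.27 (camera adjusted p = 0.0365, and adjusted p = 0.342 with an estimated correlation), and fry gave an adjusted p of 0.042. That call was lost without level replicate 2 (0.0673) or 3 (0.102), and without parabola 1 replicate 3 (0.0566) or 4 (0.105, with a median of −0.15), and without the 25% of genes with the lowest mean (0.0742).

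Among 63 chloroplast-encoded genes, ndhC (0.57 ± 0.15 SE), ndhF (0.55 ± 0.14 SE), ndhK (0.55 ± 0.13 SE) and ndhJ (0.53 ± 0.13 SE) rose after parabola 1 and 0 fell. In ndhK, level replicate 3 lay at 8.37 and the other level arrays at 7.87 to 7.95. These genes encode subunits of the chloroplast NADH dehydrogenase-like complex. When adjusted over the list alone 4 rose, and at an unadjusted p under 0.05 in limma 19 were higher and 0 lower. The list median was 0.19 (camera adjusted p = 8.31e-08, and adjusted p = 0.392 with an estimated correlation), and fry did not call it (0.11). With arrays centred on the reference genes the chloroplast median was 0.08. Nuclear photosynthesis genes, a list of 18 chosen after the data were seen, had a median of 0.16, and 2 rose and 0 fell (adjusted p = 0.0238, and adjusted p = 0.289 with an estimated correlation). The array median of 7083 rows without a gene name was 2.64 ± 0.05 (SD, n = 4) after parabola 1 and 2.48 ± 0.04 (SD, n = 4) in level flight.

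The remaining lists did not pass in camera after parabola 1, though fry called the hypoxia genes (0.00862) and the xyloglucan endotransglucosylases and expansins (0.042), both downward. Of 5 heat shock genes, AT2G29500 (HSP17.6B) fell (−0.92 ± 0.20 SE), 3 fell when adjusted over the list alone, and the list's adjusted p was 0.0756. Of 7 xyloglucan endotransglucosylase and expansin genes, which act on cell walls, XTH21 (−1.21 ± 0.23 SE) and XTH19 (−0.95 ± 0.15 SE) fell, 3 fell when adjusted over the list alone, and the adjusted p was 0.105. The 9 measured XTH genes alone, a family formed after the data were seen, passed (camera adjusted p = 0.0381, and adjusted p = 0.739 with an estimated correlation). Of 3 hypoxia genes, the pyruvate decarboxylase gene PDC2 fell (−0.42 ± 0.11 SE), 2 fell when adjusted over the list alone, and the adjusted p was 0.108. Of 6 auxin response genes, WES1 (GH3.5) rose (0.59 ± 0.12 SE), while GH3.3 (−0.75 ± 0.19 SE) and GH3.1 (−0.72 ± 0.17 SE) fell. When adjusted over the list alone 2 rose and 2 fell, with an adjusted p of 0.473 for the list. Of 13 mitochondrion-encoded genes 0 passed, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05 in limma (list adjusted p = 0.102). Of 3 reference genes 0 passed, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.322). PEX4 (UBC21), at 0.02, turned to −0.09 when arrays were centred on the reference genes.

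Centring on these 3 genes moved the median log2 change of all genes after parabola 1 from 0.00796 to −0.107, and 82.6% of called genes were then lower, against 58.3% without it. The count of changed genes rose to 2548 when all rows were tested. It was 482 with the unnamed-row median as a covariate, an alternative added after the data were seen. Over all tested genes, log2 fold changes with and without this covariate correlated at 0.854. In that fit the median SE of called genes went from 0.13 to 0.20. Their median log2 fold change, taken in each gene's direction without the covariate, went from 0.62 to 0.64.

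After parabola 3, AT1G49570 was 8.81-fold higher than in level flight (3.14 ± 0.16 SE, n = 4 and 4, adjusted p = 3.19e-09) and AT3G46190 was 7.95-fold higher (2.99 ± 0.18 SE). AT2G43140, a basic helix-loop-helix gene, rose 4.88-fold (2.29 ± 0.16 SE), and the peroxidase gene AT5G19890 rose 4.74-fold (2.25 ± 0.17 SE). AT4G27657 was 6.79-fold lower (−2.76 ± 0.28 SE, n = 4 and 4, adjusted p = 3.35e-06), and its neighbour in number AT4G27654 was 6.74-fold lower (−2.75 ± 0.21 SE). AT4G29780 was 6.05-fold lower (−2.60 ± 0.20 SE), with parabola 3 replicate 3 at 6.58 and the other 3 arrays at 5.39 to 5.48.

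The other largest rises after parabola 3 were AT1G26240, AT5G48430, AT5G41280, AT3G62460, AT5G40590 and AT2G30660, with log2 fold changes from 1.89 to 2.30. The other largest falls were AT4G25433, AT2G36690, sks15, AT2G29452, AT4G04745, AT5G62210 and AT1G05575, from −2.47 to −2.31. In all, 1850 genes changed, 742 upward and 1108 downward, of which 76 and 235 changed at least 2-fold. The groups did not overlap in 15.8% of genes, where chance gives 2.86%.

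Of the 5 genes of abscisic acid, cold and dehydration, 3 fell after parabola 3 and 5 fell when adjusted over the list alone. KIN1 (−1.15 ± 0.24 SE), KIN2 (−0.75 ± 0.11 SE) and the dehydrin gene COR47 (−0.53 ± 0.11 SE) fell, and LTI30 (−0.26) did not pass over all genes. The list median was −0.53 (camera adjusted p = 0.000203, and adjusted p = 0.0754 with an estimated correlation). Of the 7 calcium sensors and touch genes, AT1G76640 (−2.18 ± 0.22 SE), CML38 (−2.15 ± 0.20 SE), CML37 (−0.72) and CML23 (−0.53) fell and CML42 rose (0.58 ± 0.16 SE), with 4 and 1 when adjusted over the list alone. In CML37, parabola 3 replicate 3 lay at 3.02 and the other 3 arrays at 2.63 to 2.67. All lay below the medians of these arrays over the tested genes, 3.66 to 3.68, so this gene was dim. The calcium list had a median of −0.53 (camera adjusted p = 0.0111, and adjusted p = 0.0754 with an estimated correlation). Fry gave adjusted p = 0.000377 for the abscisic acid list and 8.43e-05 for the calcium list.

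Of 13 mitochondrion-encoded genes, nad9, which encodes a respiratory complex I subunit, fell after parabola 3 (−0.33 ± 0.10 SE), also when adjusted over the list alone. Others such as nad2 (−0.27), nad7 (−0.22) and nad4L (−0.17) did not pass. The median of this list was −0.14 (camera adjusted p = 0.041, and adjusted p = 0.518 with an estimated correlation), and fry did not call it (0.118). The call was lost without level replicate 1 (0.062) or 3 (0.0591) or parabola 3 replicate 2 (0.116, with a median of −0.09), after a repeated quantile normalization (0.0843, with a median of −0.075) and without the 25% of genes with the lowest mean (0.0941).

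Of 3 hypoxia genes, the lactate dehydrogenase gene AT4G17260 fell (−0.63 ± 0.15 SE), 2 fell when adjusted over the list alone, and PDC2 (−0.34) and AT3G10040 (−0.06) did not pass over all genes. As a list these genes had a median of −0.34 (camera adjusted p = 0.0488, and adjusted p = 0.131 with an estimated correlation), and fry gave an adjusted p of 0.000653. Of 5 heat shock genes, AT2G29500 (−0.84 ± 0.20 SE) and AT5G51440, or HSP23.5 (−0.67 ± 0.15 SE), fell, also when adjusted over the list alone. Their median was −0.24 (camera adjusted p = 0.0488, and adjusted p = 0.406 with an estimated correlation), and fry did not call it (0.118). Parabola 3 replicate 3 lay at 0.59 for this list and the other 3 arrays at −0.28 to −0.21. Both calls were lost without level replicate 1, 2 or 3, parabola 1 replicate 2 or 4, parabola 3 replicate 2 or 4, or parabola 10 replicate 3. Heat shock was also lost without parabola 3 replicate 1 (0.161) and hypoxia without parabola 3 replicate 3 (0.0563). The adjusted p without 1 of these arrays was from 0.0503 to 0.161. The heat shock median was −0.08 without parabola 3 replicate 2 and −0.51 without replicate 3 (adjusted p = 0.000429). Other alternatives ended both calls with medians no closer to 0. Without the 25% of genes with the lowest mean the medians were −0.34 for hypoxia and −0.45 for heat shock (0.0941 for both). With centring on the reference genes they were −0.39 (0.059) and −0.28 (0.079), and with all rows they did not move (0.0564 and 0.0623). The unnamed-row covariate ended the heat shock call (0.0514) with a median of −0.22.

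The other lists did not pass in camera after parabola 3, though fry called the xyloglucan endotransglucosylases and expansins downward (0.0184). XTH21 (−1.18 ± 0.23 SE) and XTH19 (−1.11 ± 0.15 SE) fell and EXPA7, an expansin gene of root hairs, rose (0.55 ± 0.14 SE), with 2 and 1 when adjusted over the list alone and an adjusted p of 0.0696. Of the auxin response genes GH3.1 fell (−0.61 ± 0.17 SE), also when adjusted over the list alone, and the list's adjusted p was 0.936. Its median was 0.15, while its mean was −0.04 and the test pointed down. Of the chloroplast-encoded genes 0 passed, also when adjusted over the list alone, and in limma 3 were higher and 5 lower at an unadjusted p under 0.05 (list adjusted p = 0.847). The chloroplast median was 0.02 and the test pointed down. Of the reference genes 0 passed and 0 had an unadjusted p under 0.05 (list adjusted p = 0.847).

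The count of changed genes after parabola 3 rose to 3173 when all rows were tested. With arrays centred on the reference genes, 72.8% of called genes were lower, against 59.9% without it.

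After parabola 10, AT1G49570 was 13.1-fold higher than in level flight (3.72 ± 0.17 SE, n = 3 and 4, adjusted p = 6.82e-10) and AT5G19890 was 6.64-fold higher (2.73 ± 0.18 SE). AT1G26240 rose 6.31-fold (2.66 ± 0.32 SE) and AT5G47980 rose 4.61-fold (SE 0.20 on the log2 scale). AT4G27654 was 12.2-fold lower (−3.61 ± 0.23 SE, n = 3 and 4, adjusted p = 1.57e-08), and ZCF37 was 12.0-fold lower (−3.59 ± 0.20 SE). AT3G53600 was 9.06-fold lower (−3.18 ± 0.31 SE), and the VQ motif gene AT1G17147 was 8.69-fold lower (−3.12 ± 0.17 SE).

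The other largest rises after parabola 10 were AT5G48430, AT4G20970, AT2G43140, AT3G62460, AT5G10970 and AT3G51540, with log2 fold changes from 1.93 to 2.17. The other largest falls were AT4G27657, AT1G05575, AT2G36690, AT5G62210, AT1G78410 and the receptor-like kinase gene AT5G25930, from −2.98 to −2.79. In all, 2423 genes changed, 1247 upward and 1176 downward, of which 155 and 330 changed at least 2-fold. The groups did not overlap in 24.2% of genes, where chance gives 5.71%.

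**Figure D2:**
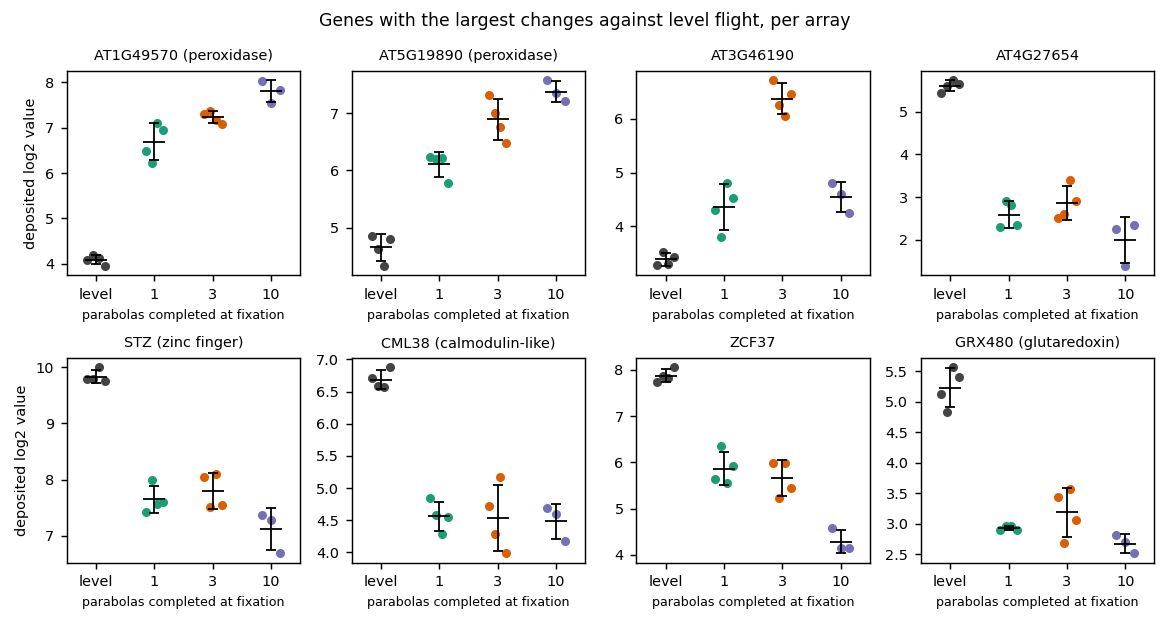
Deposited log2 values of 8 genes in each array (points) by the number of parabolas completed at fixation, with the group mean and SD (bars). The peroxidase genes AT1G49570 and AT5G19890 lie above level flight and AT4G27654, STZ, CML38, ZCF37 and GRX480 below it in all 3 parabola groups, while AT3G46190 is highest after parabola 3.

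Of the 7 calcium sensors and touch genes, 4 fell and 1 rose after parabola 10, with the same counts when adjusted over the list alone. AT1G76640 (−2.35 ± 0.24 SE), CML38 (−2.20 ± 0.21 SE), CML37 (−0.69) and CML23 (−0.51) fell and CML42 rose (0.56 ± 0.17 SE). The calcium list had a median of −0.51 (camera adjusted p = 0.00688, and adjusted p = 0.0863 with an estimated correlation), and fry gave an adjusted p of 7.22e-05. Of 5 heat shock genes, AT2G29500 (−1.79 ± 0.22 SE) and AT5G51440 (−0.82 ± 0.16 SE) fell, 3 fell when adjusted over the list alone, and the median was −0.59. The camera adjusted p was 0.00609, with adjusted p = 0.299 with an estimated correlation and 0.0114 in fry. Of the genes of abscisic acid, cold and dehydration, KIN1 (−1.37 ± 0.26 SE) and KIN2 (−0.49 ± 0.11 SE) fell, and 3 fell when adjusted over the list alone. Their list median was −0.48 (camera adjusted p = 0.0153, and adjusted p = 0.299 with an estimated correlation), with 0.0114 in fry. That call was lost without level replicate 3 (0.0509) or parabola 10 replicate 3 (0.0638).

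Of the 63 chloroplast-encoded genes, 7 fell after parabola 10 and 0 rose, and 6 fell when adjusted over the list alone. The photosystem II subunit gene psbM (−1.30 ± 0.25 SE), rps16 (−0.65 ± 0.17 SE), rps18 (−0.61 ± 0.15 SE) and psbI (−0.42 ± 0.10 SE) were among them. In psbM, level replicate 3 lay at 8.47 and the other level arrays at 7.89 to 7.98. The chloroplast list had a median of −0.15 (camera adjusted p = 0.0038, and adjusted p = 0.631 with an estimated correlation), and fry did not call it (0.326). The median was −0.07 without level replicate 3 and −0.02 without parabola 10 replicate 2, where the call was lost (0.134 and 0.394), and −0.32 without parabola 10 replicate 3 (2.94e-09). Level replicate 3 lay at 0.20 for this list and the other level arrays at −0.11 to −0.10. The 18 nuclear photosynthesis genes had a median of 0.18, and 3 rose and 0 fell (adjusted p = 0.304).

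The other lists did not pass in camera after parabola 10, though fry called the hypoxia genes downward (0.0114). XTH19 (−1.53 ± 0.16 SE) and XTH21 (−1.17 ± 0.25 SE) fell and EXPA7 rose (0.81 ± 0.15 SE), with 2 and 1 when adjusted over the list alone and an adjusted p of 0.233. PDC2 fell (−0.44 ± 0.12 SE), 2 hypoxia genes fell when adjusted over the list alone, and that list's adjusted p was 0.198. Of the auxin response genes, GH3.3 fell (−1.53 ± 0.21 SE) and LBD29, a transcription factor gene of lateral root formation, rose (0.73 ± 0.14 SE). When adjusted over the list alone 2 rose and 1 fell, with an adjusted p of 0.806, and the median of 0.01 differed in sign from the mean of −0.14 and from the test. Of the mitochondrion-encoded genes nad9 fell (−0.34 ± 0.10 SE), 0 passed when adjusted over the list alone, and the list's adjusted p was 0.0846. Of the reference genes 0 passed in limma and 1 had an unadjusted p under 0.05 (list adjusted p = 0.806).

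The count of changed genes after parabola 10 rose to 4460 when all rows were tested. With arrays centred on the reference genes, 65.1% of called genes were lower, against 48.5% without it.

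**Figure D3:**
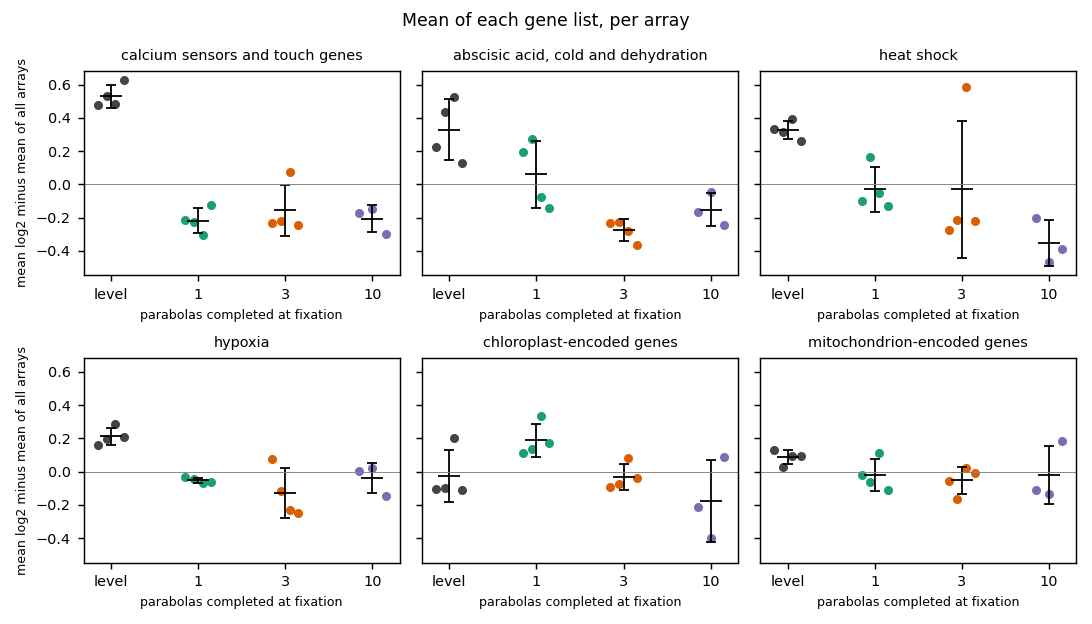
Mean log2 value of each of 6 gene lists in each array, minus its mean over all arrays (points), by the number of parabolas completed at fixation, with the group mean and SD (bars). The calcium sensors and touch genes lie at 0.53 ± 0.07 in level flight and at −0.22 ± 0.08 after parabola 1.

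Of the lists with 1 or 2 measured members, LZY3 (AT1G72490), a LAZY family gene that acts in root gravitropism, fell after parabola 1 (−0.83 ± 0.17 SE), parabola 3 (−0.78 ± 0.17 SE) and parabola 10 (−1.65 ± 0.18 SE). LZY2 (AT1G17400) did not pass, with 0.02, 0.03 and −0.07. The glutathione transferase gene GSTU25, of the list of reactive oxygen and detoxification, did not pass after parabola 1 (−0.46) and fell after parabola 3 (−0.84 ± 0.24 SE) and parabola 10 (−2.14 ± 0.26 SE). STZ, given above, was the only measured member of the rapid stress transcription factors, and it fell in all 3 contrasts (−2.19, −2.04 and −2.72). AT3G15450, of the list of dark and sugar starvation, rose after parabola 3 (0.46 ± 0.11 SE) and parabola 10 (0.42 ± 0.12 SE). Of the root hair markers, EXPA7 rose after parabolas 3 and 10 (given above) and EXPA18 did not pass (−0.02, −0.22 and 0.02). The remaining measured members did not pass in any contrast against level flight. After parabola 10 they were at −0.20 for AT2G21640 (UPOX), −0.16 for PDF1.2 of the salicylate list, −0.23 for GI of the circadian clock, 0.33 for RCA of the shoot markers and 0.24 for AT1G65570 of the root cap markers.

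The contrasts against level flight shared many genes. AT1G49570 rose and AT4G27654, GRX480, STZ and ZCF37 fell in all 3, with ZCF37 at −2.01, −2.21 and −3.59 and GRX480 at −2.30, −2.04 and −2.56. In total 779 genes changed the same way in all 3 contrasts, 266 upward and 513 downward, out of 3299 called in at least 1, and 6 were called in opposite directions. Independent lists of these sizes would share 1.94 upward and 3.82 downward. Because the contrasts use the same level arrays, the correlations of log2 fold changes across genes (0.763, 0.764 and 0.826) were set against simulated unchanged groups, whose highest values were 0.737, 0.701 and 0.715. Genes are not independent replicates. With separate pairs of level arrays for the 2 contrasts compared, 433 to 652 genes were shared, where independent lists would share at most 54.1. All level pools came from 1 tube, so a deviation of that whole tube would still be shared by both pairs. The count of genes changed in all 3 contrasts was 362 with the unnamed-row median as a covariate and 1313 when all rows were tested.

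Between parabola 3 and parabola 1, AT3G46190 was 4.04-fold higher after parabola 3 (2.02 ± 0.18 SE, n = 4 and 4, adjusted p = 1.69e-05), and AT5G41300, AT2G44340, the lectin-like gene AT5G49850 and AT2G43140 rose by 1.61 to 1.88 on the log2 scale. GH3.17, which encodes an enzyme that conjugates auxin to amino acids, was 2.99-fold lower (−1.58 ± 0.15 SE, n = 4 and 4, adjusted p = 1.69e-05). AT3G13403, AT1G49450, AT1G52342 and AT5G15190 were lower too, from −1.50 to −1.26. In all, 126 genes were higher and 159 lower, and the groups did not overlap in 7.54% of genes, where chance gives 2.86%. Of the chloroplast-encoded genes, psbM (−1.06 ± 0.23 SE), psbN (−0.54 ± 0.13 SE) and psbI (−0.41 ± 0.10 SE) fell, 0 rose and 10 fell when adjusted over the list alone. Their median was −0.20 (camera adjusted p = 5.03e-12, and adjusted p = 0.778 with an estimated correlation), and fry did not call them (0.327). The chloroplast median was −0.13 with arrays centred on the reference genes and also with the unnamed-row median as a covariate. Of the genes of abscisic acid, cold and dehydration 0 passed over all genes in limma, 3 were lower at an unadjusted p under 0.05 and 3 fell when adjusted over the list alone, with a list median of −0.27 (camera adjusted p = 0.00398, and adjusted p = 0.443 with an estimated correlation). Fry did not call it (0.105). With the unnamed-row median as a covariate that list call was lost (0.221).

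The count of 285 genes between parabola 3 and parabola 1 was 134, 171 or 158 without parabola 1 replicate 1, 2 or 3, and 171, 162 or 151 without parabola 3 replicate 2, 3 or 4. It was 160 with the arrays of these groups alone and 19 with the unnamed-row median as a covariate. Over all tested genes, log2 fold changes with and without this covariate correlated at 0.717. With this covariate the median SE of called genes went from 0.14 to 0.20. Their median log2 fold change, taken in each gene's direction without the covariate, went from 0.66 to 0.61. With arrays centred on the reference genes 32.1% of called genes were lower, against 55.8% without it.

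Between parabola 10 and parabola 3, AT2G01023 was 3.21-fold higher after parabola 10 (1.69 ± 0.38 SE, n = 3 and 4, adjusted p = 0.0349), and AT5G47980 was 2.47-fold higher (1.31 ± 0.20 SE). The spread of AT2G01023 includes parabola 1 replicate 4 at 2.67, with the other 3 arrays of that group at 4.14 to 4.23. AT1G45015, SRS3 and AT3G01260 rose by 1.12 to 1.17 on the log2 scale. The ATPase gene AT3G28510 was 4.37-fold lower (−2.13 ± 0.31 SE, n = 3 and 4, adjusted p = 0.00168), and AT5G49850 (−1.84), AT3G46190 (−1.82), AT2G43120 (−1.61) and the acyltransferase gene AT5G07860 (−1.57) were lower too. In all, 98 genes were higher and 95 lower, and the groups did not overlap in 9.67% of genes, where chance gives 5.71%. Of the chloroplast-encoded genes 0 passed, also when adjusted over the list alone, and in limma 0 were higher and 8 lower at an unadjusted p under 0.05. Their median was −0.14 (camera adjusted p = 6.81e-06, and adjusted p = 0.98 with an estimated correlation), and fry did not call them (0.593). Without parabola 10 replicate 2 the median was −0.05 and the call was lost (0.53). It was −0.09 without parabola 10 replicate 1 or parabola 3 replicate 3 and −0.25 without parabola 10 replicate 3.

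The count of 193 genes between parabola 10 and parabola 3 was 114 or 89 without parabola 10 replicate 1 or 2, and 104 or 127 without parabola 3 replicate 3 or 4. It was 69 with the arrays of these groups alone, 118 with array weights, 113 with arrays centred on the reference genes and 81 with the unnamed-row median as a covariate. Over all tested genes, log2 fold changes with and without this covariate correlated at 0.95. With this covariate the median SE of called genes went from 0.144 to 0.156. Their median log2 fold change, taken in each gene's direction without the covariate, went from 0.76 to 0.73. Under reference-gene centring 62.8% of called genes were lower, against 49.2% without it.

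Between parabola 10 and parabola 1, AT4G20970, a basic helix-loop-helix gene, was 3.49-fold higher after parabola 10 (1.80 ± 0.27 SE, n = 3 and 4, adjusted p = 0.00118). AT4G39675, AT3G27950, AT5G48430 and AT5G04310 rose by 1.54 to 1.75 on the log2 scale. AT5G66780 was 5.26-fold lower (−2.40 ± 0.26 SE, n = 3 and 4, adjusted p = 0.000188), with parabola 1 replicate 2 at 7.54 and the other 3 arrays at 6.93 to 7.01. The genes AT1G78922 (−2.16), AT4G36791 (−2.08), AT4G30097 (−1.82) and psbM (−1.69) were lower too. In all, 287 genes were higher and 302 lower, and the groups did not overlap in 14.7% of genes, where chance gives 5.71%. Of the 63 chloroplast-encoded genes 14 fell and 0 rose, and 33 fell when adjusted over the list alone, with rps16 2-fold lower, ndhG at −0.99 ± 0.17 SE and rps18 at −0.82 ± 0.15 SE. Their median was −0.38 (camera adjusted p = 2.86e-22, and adjusted p = 0.629 with an estimated correlation), and fry did not call them (0.105). The chloroplast median was −0.24 without parabola 10 replicate 2 and −0.23 with the unnamed-row median as a covariate. Of 5 heat shock genes AT2G29500 fell (−0.88 ± 0.22 SE) and 2 fell when adjusted over the list alone, with a list median of −0.17 (camera adjusted p = 0.044, and adjusted p = 0.726 with an estimated correlation), and fry did not call it (0.527). That call was lost without level replicate 4 (0.0502), parabola 1 replicate 2 (0.119) or 3 (0.0683) or parabola 10 replicate 2 (0.13) or 3 (0.0952). Median centring (0.0596), removal of the 25% of genes with the lowest mean (0.141, with a median of −0.28) and testing all rows (0.218) ended it too. With the unnamed-row median as a covariate the heat shock median was −0.66 (adjusted p = 0.000198).

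The count of 589 genes between parabola 10 and parabola 1 was 364 or 321 without parabola 1 replicate 1 or 2, 282 or 274 without parabola 10 replicate 1 or 2, 366 with the arrays of these groups alone and 1525 when all rows were tested. With the unnamed-row median as a covariate it was 1. Over all tested genes, log2 fold changes with and without this covariate correlated at 0.621. The median SE of called genes went from 0.14 to 0.24. Their median log2 fold change, taken in each gene's direction without the covariate, went from 0.63 to 0.51. With arrays centred on the reference genes 37.6% of called genes were lower, against 51.3% without it.

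**Figure D4:**
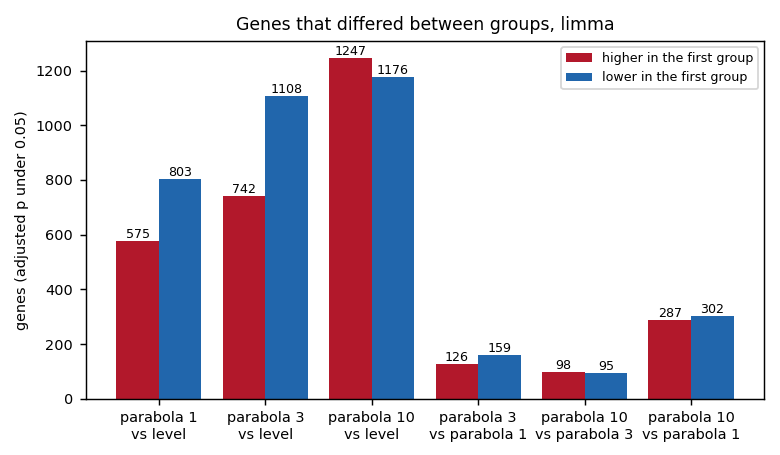
Number of genes with an adjusted p under 0.05 in limma in each of the 6 contrasts, higher (red) or lower (blue) in the first group named. Counts against level flight run from 575 higher genes after parabola 1 to 1247 after parabola 10.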

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

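The tests on the share of organelle transcripts, on parabola 3 replicate 1 and on the array median of unnamed rows were chosen only after the results were seen.

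Among the genes that changed most against level flight, several also differed between parabola groups. After parabola 3, compared with parabola 1, AT3G46190 was higher by 2.02 on the log2 scale, AT2G43140 by 1.61, AT5G48430 by 1.60, AT2G30660 by 1.57, AT5G40590 by 1.54, AT5G41280 by 1.53 and AT5G19890 by 0.79. AT5G47980 fell by 0.88 and AT5G26290 fell by 0.77. After parabola 10, compared with parabola 3, AT5G47980 was higher by 1.31, AT5G26290 by 0.68 and AT5G10970 by 0.53. AT3G46190 fell by 1.82, AT2G30660 fell by 1.43, ZCF37 fell by 1.37, AT5G25930 fell by 1.13, AT5G41280 fell by 1.07 and AT1G17147 fell by 0.95. After parabola 10, compared with parabola 1, AT4G20970 was higher by 1.80, AT5G48430 by 1.59, AT5G40590 by 1.45, AT2G43140 by 1.36, AT5G19890 by 1.27, AT1G49570 by 1.12 and AT5G10970 and AT3G51540 by 0.59 each. ZCF37 fell by 1.58, AT5G25930 fell by 1.14, AT1G17147 fell by 1.13 and AT3G61898 fell by 1.103. Each of these differences passed the test of the difference itself, with adjusted p from 1.69e-05 to 0.0419.

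Lists differed between parabola groups as well. The median of the abscisic acid, cold and dehydration genes fell by 0.27 from parabola 1 to parabola 3, and that of the heat shock genes fell by 0.17 from parabola 1 to parabola 10. The chloroplast-encoded genes changed by −0.20 from parabola 1 to parabola 3, −0.14 from parabola 3 to parabola 10 and −0.38 from parabola 1 to parabola 10. None of these list calls held with an estimated correlation, where the adjusted p were 0.443, 0.726, 0.778, 0.98 and 0.629.

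In some genes 1 array lay far from the other 3 of its group. In level flight, replicate 3 was high for psbM (8.47 against 7.89 to 7.98), ndhK (8.37 against 7.87 to 7.95) and psbI (11.86 against 11.69 to 11.71), replicate 1 was high for AT4G34270 (6.96 against 6.84 to 6.86) and replicate 4 was low for AT1G49450 (5.39 against 6.20 to 6.32). After parabola 1, replicate 4 was low for AT2G01023 (2.67 against 4.14 to 4.23) and AT5G19890 (5.78 against 6.20 to 6.23). Replicate 3 was low for AT3G53600 (3.51 against 4.35 to 4.47) and high for rps16 (7.95 against 7.86 to 7.87), and replicate 2 was high for AT5G66780 (7.54 against 6.93 to 7.01) and LTI30 (6.46 against 6.10 to 6.16). After parabola 3, replicate 3 was high for AT4G29780 (6.58 against 5.39 to 5.48) and CML37 (3.02 against 2.63 to 2.67). Replicate 1 was high for GH3.3 (7.13 against 6.26 to 6.34) and low for PDC2 (3.32 against 3.40 to 3.41). Replicate 4 was low for AT5G10970 (6.91 against 7.10 to 7.13) and COR15A (2.49 against 2.65), and replicate 2 was low for nad2 (10.37 against 10.66 to 10.71).

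Of the list scores, parabola 3 replicate 3 was high for heat shock (0.59 against −0.28 to −0.21) and for calcium sensors and touch genes (0.07 against −0.25 to −0.22). Level replicate 3 was high for chloroplast-encoded genes (0.20 against −0.11 to −0.10), and parabola 1 replicate 4 was low for the reference genes (−0.01 against 0.07 to 0.08). In all, 22 of 357 groups of 4 arrays had such an array, and chance gives about 1 in 20 groups. Level replicate 3 and parabola 3 replicate 3 had 4 each. The groups are not independent, since list scores hold named genes. The 4 of level replicate 3 are psbM, ndhK, psbI and the chloroplast list that holds them. The share of 1 in 20 is therefore only a rough guide.

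The array median of the 7083 unnamed rows was higher after parabola 1 than in level flight by 0.16, with all 4 arrays above every level array (exact permutation p = 0.0286, two-sided). This is the smallest p that the 70 splits can give. Parabola 3 replicate 1, at 2.58, also lay within the parabola 1 range of 2.56 to 2.68, while the parabola 3 mean was 2.48.

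A chance split of these pools was argued against for each count of changed genes, but not excluded. The real split of the arrays alone reached it, 1 of 35 splits for each pair of groups, which is the smallest share possible. Mixed splits carry the group difference in their spread, which lowers their counts. Chance differences between tubes are not covered, since each group came from 1 tube. The 1378 genes after parabola 1 stood against at most 1 in any other split, 1850 after parabola 3 against 1, and 2423 after parabola 10 against 576. Between parabola groups, 285 stood against 1, 193 against 28 and 589 against 17, and the 2601 genes of the F-test against 122 over 100 drawn splits. For the number of lists past the threshold the splits gave no such argument. The 3 lists after parabola 1 were reached in 4 of 35 splits, the 5 after parabola 3 in 5 and the 4 after parabola 10 in 4, with 3, 5 and 4 as the highest of the other splits.

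A pattern looked at more closely was the set of 779 genes that differed from level flight the same way after every parabola sampled. AT1G49570, AT4G27654, STZ and GRX480 were among them. Chance values of the shared level arrays as the whole cause were argued against by the covariance of log2 fold changes across genes, at least 0.0734, where simulated unchanged groups gave at most 0.0216. A single deviating level array was argued against too, since at least 604 genes were shared without any 1 of them (604 without level replicate 1). The labels give 1 tube per condition, so fixation tube and time on board cannot be told apart from the parabolas. A response to the parabolas stays open as untested.

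Chloroplast-encoded genes such as psbM, rps16 and ndhG were lower after parabola 10 than after parabola 1, with a list median of −0.38 (bootstrap 95% interval over genes −0.46 to −0.27). Had shoot tissue left on the roots been the whole cause, nuclear photosynthesis genes would have fallen about as much, and their median was −0.068 (−0.122 to 0.096). The mitochondrion-encoded genes were at 0.018 (−0.106 to 0.032). These intervals are over correlated genes and leave out the spread between arrays. The nuclear photosynthesis score was 0.07 ± 0.09 (SD, n = 4) after parabola 1 and 0.06 ± 0.20 (SD, n = 3) after parabola 10. Its mean hardly moved, but with this spread over few arrays shoot tissue was not excluded. After parabola 10 the mitochondrial list score was −0.02 ± 0.18 (SD, n = 3). Like the chloroplast score, it was lowest in replicate 2 and highest in replicate 3. A changed share of organelle transcripts was therefore not excluded. A single deviating array was argued against, since the median closest to 0 without 1 of the 7 arrays was −0.24, without parabola 10 replicate 2. With the unnamed-row median as a covariate the median went to −0.23, and with an estimated correlation the call was lost (adjusted p = 0.629), so a technical shift shared by these correlated transcripts stays open. A difference in plastid transcripts between the parabolas, confounded with the tubes, stays open as untested.

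Parabola 3 replicate 1 correlated over all rows with the parabola 1 arrays at 0.985 and with its own group at 0.98, and over the unnamed rows at 0.934 and 0.895. Over the tested genes the 2 values were 0.989 and 0.99. A parabola 1 library under a parabola 3 label was argued against by the genes that separated the groups, along which this array lay 0.505 above the highest parabola 1 array (SD of that group 0.0989). It lay 0.027 below the lowest of the other parabola 3 arrays (SD 0.0692), so unspecific noise of this array cannot be told apart from ordinary spread. No biological explanation was tested.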

How the results depend on the processing

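The covariate of unnamed rows was added only after the data were seen. AT1G49570, AT4G27654 and the other named genes and lists apart from the counts below kept direction and side of the threshold in 4938 gene comparisons with an alternative and 715 list comparisons. Calls were lost in 181 and 65, gained in 51 and 9, and 11 and 11 reversed. The calcium sensors and touch genes after parabola 1 kept their call in all 25 alternatives, with adjusted p from 0.000113 to 0.0219. The cause of a change was not tested unless stated.

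With all rows, 2548 genes changed after parabola 1, 3173 after parabola 3, 4460 after parabola 10 and 1525 between parabolas 10 and 1, with 4892 by the F-test and 1313 in all 3 contrasts. More features were tested. At an adjusted p under 0.01, by construction fewer passed, 763, 923 and 1356 against level flight, 82, 60 and 154 between parabolas 3 and 1, 10 and 3, and 10 and 1, 1359 by the F-test and 433 in all 3 contrasts. At 2-fold or more the counts were 257, 311, 485, 55, 41 and 67, and 168 in all 3 contrasts, and the F-test has no single fold change. With the arrays of 2 groups alone, fewer arrays gave 160, 69 and 366 between parabola groups. Array weights gave 118 genes between parabolas 10 and 3, and centring on the reference genes 113. The covariate gave 482 after parabola 1, 19, 81 and 1 between parabola groups and 362 in all 3 contrasts.

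The lists past the threshold after parabola 3 numbered 3 with centring on the reference genes, 2 without the 25% of genes with the lowest mean and 3 with all rows. Camera with an estimated correlation left 1 list after parabola 1, 0 after parabola 3 and 0 after parabola 10, against 3, 5 and 4 with limma's preset.

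Centring on the reference genes moved the share of lower genes to 82.6% after parabola 1 (58.3% without it), 72.8% after parabola 3 (59.9%), 65.1% after parabola 10 (48.5%), 32.1% between parabolas 3 and 1 (55.8%), 62.8% between 10 and 3 (49.2%) and 37.6% between 10 and 1 (51.3%).

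Without 1 array, the counts ran from 1023 to 1417 after parabola 1, 1369 to 1922 after parabola 3, 1723 to 2472 after parabola 10, 134 to 384 between parabolas 3 and 1, 89 to 247 between 10 and 3, 274 to 761 between 10 and 1, 1977 to 2776 by the F-test and 604 to 746 in all 3 contrasts. Between parabolas 3 and 1, the count was 134, 171 or 158 without parabola 1 replicate 1, 2 or 3, and 171, 162 or 151 without parabola 3 replicate 2, 3 or 4. Between 10 and 3 it was 104 or 127 without parabola 3 replicate 3 or 4, and 114 or 89 without parabola 10 replicate 1 or 2. Between 10 and 1 it was 364 or 321 without parabola 1 replicate 1 or 2, and 282 or 274 without parabola 10 replicate 1 or 2. Lists numbered 2 to 4 after parabola 1, 2 to 5 after parabola 3 and 2 to 4 after parabola 10. After parabola 3 there were 2 without level replicate 1 or parabola 3 replicate 2, and 3 without level replicate 2 or 3, parabola 1 replicate 2 or 4, parabola 3 replicate 4 or parabola 10 replicate 3. After parabola 10 there were 2 without level replicate 3.

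With the replicate number as a block the counts were 1375, 1820, 2266, 278, 181 and 537, with 2522 by the F-test and 769 in all 3 contrasts. The numbers gave no clear sign of pairing. Of 21 pairs of arrays with a shared number, 1 had a residual correlation over 0.1 (−0.0761 to 0.106). In 8 of them the array of the same number correlated best, so a weak pairing was not excluded.

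Results that reversed had not passed the threshold on either side. PEX4 turned to 0.007 after parabola 3 with a repeated quantile normalization and 0.024 without parabola 3 replicate 4 (−0.098 to 0.024 without 1 array), and after parabola 1 to −0.094 with reference-gene centring, −0.012 without level replicate 4 and −0.004 without parabola 1 replicate 3 (−0.012 to 0.048). With the same centring AT1G53540 turned to −0.004 and AT3G10040 to −0.013 after parabola 1. AT1G53540 was −0.109 without parabola 1 replicate 2 (−0.109 to 0.213 without 1 array), and AT4G34270 −0.053 with the covariate. In the test of auxin response genes after parabola 3 the direction turned with medians of 0.142 by quantile normalization, 0.147 with all rows or without parabola 10 replicate 1, 0.165 without level replicate 1 and 0.197 without parabola 3 replicate 2 (0.079 to 0.197 without 1 array), and after parabola 10 with 0.196 without parabola 10 replicate 3 (−0.186 to 0.196). For chloroplast-encoded genes after parabola 3 it turned with 0.058 by quantile normalization, 0.023 without the 25% of genes with the lowest mean, 0.098 without level replicate 3, and 0.067 or 0.018 without parabola 3 replicate 1 or 2 (−0.021 to 0.098 without 1 array). ATHSP22.0 was 0.021 after parabola 3 without parabola 3 replicate 1 (−0.230 to 0.021 without 1 array), and COR47 0.013 after parabola 10 without parabola 10 replicate 3 (−0.272 to 0.013).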

Other observations

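The families of genes with a shared symbol and the lists of peroxidases, VQ motif proteins and core hypoxia loci were chosen after the data were seen, as was the test on unnamed rows.

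PUB23, PUB24 and PUB22 encode U-box ubiquitin ligases that dampen immune signalling, and all 3 fell after parabola 1 and after parabola 10. PUB23 was 3.40-fold lower after parabola 1 (−1.76 ± 0.13 SE, n = 4 and 4), 3.46-fold lower after parabola 3 (−1.79 ± 0.13 SE) and 5.76-fold lower after parabola 10 (−2.53 ± 0.14 SE, n = 3 and 4). PUB24 was at −1.21, −1.20 and −1.82, and PUB19 at −0.77, −0.96 and −1.12. PUB22 was at −1.10 and −1.33 after parabolas 1 and 10, and did not pass after parabola 3 (−0.39). Of 10 measured PUB genes, 4 fell after parabola 1, 3 after parabola 3 and 4 after parabola 10, and 0 rose. In camera the family had adjusted p = 0.00253, 0.12 and 0.018 over 61 families, and adjusted p = 0.195, 0.579 and 0.292 with an estimated correlation.

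The β-tubulin gene TUB1 was 1.83-fold lower after parabola 1 (−0.87 ± 0.11 SE, n = 4 and 4), 2.36-fold lower after parabola 3 (−1.24 ± 0.11 SE) and 2.17-fold lower after parabola 10. TUB9 fell too, by 0.38, 0.48 and 0.52 on the log2 scale, and TUB7 fell by 0.49 and 0.45 after parabolas 1 and 3. Of 5 measured TUB genes, 3, 4 and 2 fell in the 3 contrasts, with adjusted p = 0.00601, 0.00547 and 0.018 for the family, and adjusted p = 0.233, 0.365 and 0.292 with an estimated correlation. Against level flight neither family's median changed direction under any scaling tried. Between parabolas 10 and 1 the PUB median of −0.011 turned to 0.034 with centring on the reference genes.

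After parabola 1 the XTH, CML and RPS families passed too, each with a camera adjusted p of 0.0381, and most of their named members belong to lists given above. XTH21, XTH19 and XTH16 (−0.60 ± 0.17 SE, n = 4 and 4) fell among 9 XTH genes, with a median of −0.60, adjusted p = 0.739 with an estimated correlation and 0.0445 in fry. CML38, CML37 and CML23 fell among 6 CML genes, with a median of −0.34, adjusted p = 0.233 with an estimated correlation and 0.000782 in fry. The 7 RPS genes, such as rps4 and rps16, are all members of the list of chloroplast-encoded genes and add no separate result. They had a median of 0.31, and 1 of them rose when adjusted over the list alone but not over all genes. For RPS the adjusted p = 0.861 with an estimated correlation, and fry did not call it (0.149). In camera these 3 families did not pass after parabola 3 or parabola 10, where fry called CML (0.00384 and 0.0116). Families were not tested between parabola groups.

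Because AT1G49570 and AT5G19890 were among the largest rises, a rise of the whole class III peroxidase family was tested on 61 members not seen before. After parabola 10 their median was 0.082 (bootstrap 95% interval over genes −0.07 to 0.18), with 13 higher and 9 lower past the threshold. Over all 16550 genes, 1247 were higher and 1176 lower. Fry pointed up without a call (adjusted p = 0.129). The interval leaves out the spread between arrays. The 9 members that fell argued against a rise of the whole family against level flight. After parabola 1 their median against level flight was −0.11, with 2 higher and 10 lower past the threshold (camera adjusted p = 0.0238, and adjusted p = 0.0906 with an estimated correlation), and fry gave 0.000778. Between parabolas 10 and 1, AT4G33420 (0.72 ± 0.12 SE), AT2G37130 (0.61 ± 0.12 SE), AT1G30870, AT4G37530, AT4G25980 and PRXR1 rose and 0 of the unseen members fell. The list median was 0.13 (camera adjusted p = 0.00256, and adjusted p = 0.0168 with an estimated correlation). A lower start after parabola 1 followed by a rise, not a rise of the whole family above level flight, is therefore a hypothesis for other samples.

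The VQ motif genes AT1G17147 and AT1G78410 were among the largest falls, and a fall of the family was tested on 10 members not seen before. Their median after parabola 10 was 0.033 (−0.554 to 0.331), with 2 higher and 3 lower past the threshold, while their mean was −0.07 and the test pointed down, so a fall of the family stays open. Seedlings in closed tubes could have met falling oxygen over time on board. The median of 20 core hypoxia loci after parabola 10 was −0.162 (−0.293 to 0.121), with 2 higher (AT1G19530 at 1.51 and AT4G27450 at 1.27) and 5 lower past the threshold and a camera adjusted p of 0.304. Of the 3 measured genes of the hypoxia list, 2 were lower and 1 higher (0.14) after parabola 10. Their median was −0.44, with PDC2 lower past the threshold and a downward call in fry (0.0114) but not in camera (0.198). LDH (AT4G17260) fell after parabola 3 (−0.63). With members moving both ways and 3 measured genes on the planned list, a low-oxygen response was not excluded.

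Unnamed rows and chloroplast-encoded genes were both higher after parabola 1, and a shift shared by both was tested over 15 arrays as deviations from group means. Pearson's r was 0.174 (permutation p = 0.538, 95% interval −0.413 to 0.641) and Spearman's rho was 0.107 (permutation p = 0.729), with 1 relation computed. Without the 2 arrays farthest from the median r was 0.476, so these data leave a shared shift open.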
